A study of Homo sapiens with 12 samples.

How the data were processed

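Poly(A)-selected RNA from isogenic K562 cells was sequenced with Illumina libraries, per the labels' protocols, in 12 samples: SF3B1 WT and K700E cells, each with DMSO or 13 nM H3B-8800, in 3 replicates. Samples were grouped by genotype and agent as the labels give them. The submitters' processing notes name the aligner STAR and the human genome build hg19; versions are not given in the sources used here. How reads were assigned to sites, filtered or counted is not given either.

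The authors deposited 1 file per sample that gives a percent value for each of 2372464 features. A feature is named by chromosome, start, end, strand and the side of the splice site it belongs to. From the values, the features of one site summed to 100 percent or to 0 in every library, so each deposited value is the percent of that site's reads that support the feature, and a site at 0 had no reads. Features that span 2 nt are unspliced exon-intron boundaries (739636 features), and the others are 883516 distinct splice junctions at 776344 sites. Coordinates are printed as the 1-based first and last base of the intron on hg19. Read counts cannot be had from percentages, so depth is unknown, and no interval or detection floor is given. Sites with reads, 347627 to 399606 per library, are the only sign of depth used, and a site with few reads can take a high or low percentage by sampling alone.

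The count test planned before the data were examined needs counts, so limma on transformed percentages, listed beforehand as the other test, was used. It was limma 3.58.1 in R 4.3.3 on log2(percent + 1), with group means for all 4 groups in one fit, trend and robust options on and Benjamini-Hochberg adjustment. A feature was called at adjusted p below 0.05 and a difference of at least 10 percentage points. Log2 differences on this scale understate changes from low values. The planned minimum of reads per site could not be applied and was replaced by reads at the site in all 12 libraries. A junction was tested where its share was at least 5 percent in 3 or more libraries and at most 95 percent in 3 or more. It was tested at its donor and at its acceptor and counted once, which gave 137948 junctions. Junctions were classed from coordinates against the most used junction of each site in the WT DMSO group. Intron retention was the mean of the unspliced shares at both ends of an intron whose junction was the most used at both sites. It was measured at 104520 introns and tested at the 44263 with at least 5 percent in 3 or more libraries.

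The deposited files do not pair features with gene names, and the annotation at hand is of another build than hg19. Gene names, gene lists, cell type markers, changes per gene and exon, intron or UTR annotation were therefore not analysed here, although lists had been fixed beforehand. In place of the planned rule for named genes, the 2 largest rises and 2 largest falls that passed are given per comparison, not overlapping on a strand: junctions for the mutation, introns for the drug. That reduction was chosen after the values were seen. The set of mutant-associated junctions was taken over the whole genome in place of the planned gene list.

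Library means were compared by exact permutation tests, the interaction by relabelling genotypes within each treatment (400 relabellings), acceptor distances by Fisher's exact test, and intron lengths by permutation with 100000 resamples, all two-sided. Libraries were compared in pairs over features with reads, and none was a copy of another: Pearson's r between libraries of a group, across features that are not independent, was 0.972 to 0.986. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

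The limma step was tested on simulated data built from the real means and spreads. For the mutation, with 200 of 215294 junction tests changed, changes of 15, 25 and 40 points were recovered in 0, 0 and 3.03% of cases by limma, with 2 true and 3 false calls. At an unadjusted p under 0.05 the real mutation comparison had 18819 junction tests. With 200 of 44263 introns changed, 14.9%, 34.3% and 45.5% were recovered, with 63 true and 3 false calls. For the drug in K700E cells, with 20000 junction tests changed, 2.67%, 16.0% and 33.4% were recovered and 4.17% of calls were false. With 6000 introns changed, 39.8%, 62.5% and 75.5% were recovered and 2.15% of calls were false. In these simulations most rare junction changes were missed. Changes were added only to features that already held a moderate share in WT DMSO libraries, none near 0. From a low share the same rise in points is a larger log2 difference, so these rates do not cover such features.

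Alternatives were a difference of 5 or 20 points, the replicate number as a block, each replicate left out, other distance windows and other choices of the mutant-associated set, all planned. Added after seeing the data were limma on the percent values or their log-odds, shares among spliced reads only, the lower of the unspliced shares at an intron's ends, no usage filter, fits of only the groups compared, introns matched on retention under DMSO, and intron lengths without each replicate. A first version of the spliced-read fit kept constant and undefined values and gave far fewer calls. It was corrected by requiring spliced reads in all libraries and the same usage filter.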

Results

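Polyadenylated RNA was sequenced from K562 cells, a human myelogenous leukaemia line, in isogenic versions that carried either wild-type (WT) SF3B1 or SF3B1 with the K700E substitution. SF3B1 is a core component of the U2 small nuclear ribonucleoprotein, which recognises the intron branch point near the acceptor (3′) splice site. Cells of each genotype received DMSO or 13 nM H3B-8800, a splicing modulator, which gave 4 groups of 3 libraries. The readout was the use of splice sites: the share of a site's reads that were joined across each junction or were left unspliced at the exon-intron boundary. Each library held the same 2372464 features at 776344 splice sites. Between 347627 and 399606 sites had reads in a library, from WT H3B-8800 replicate 1 at the low end to K700E DMSO replicate 3 at the high end, and 249312 sites had reads in all 12. The values are percentages, so the number of reads behind each one is unknown. Group values are means ± SD over 3 libraries. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

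The first comparison, K700E against WT cells under DMSO, addresses the mutation without the drug, with 1 isogenic line per genotype, so that line and mutation cannot be told apart. Junctions differed in both directions between the genotypes: 511 were higher and 474 lower in K700E cells, of 137948 tested (limma, adjusted p below 0.05 and at least 10 points). Among the higher junctions, 272 of 511 (53.2%) were of the alternative acceptor class, which made up 14.5% of all tested junctions. Such a junction is the most used at its acceptor but not at its donor in WT DMSO cells. The class sets no limit on distance, so it can also hold junctions to another exon. Exon-skipping junctions made up 8.22% of the higher junctions, against 14.2% of those tested. A junction already used most has less room to rise. With those most used at both ends in WT cells left out, a choice made after the data were seen, alternative acceptors were 62.2% of the higher junctions and 31.4% of those tested. The balance of directions depended on the libraries: 403 to 440 junctions were higher and at most 213 lower without single WT DMSO replicates, and 286 to 305 higher and 317 to 354 lower without single K700E DMSO replicates.

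The largest rises were at alternative acceptors. The junction over the intron at chromosome 2, 17935613 to 17941178 (hg19, plus strand), took 3.26% ± 3.70 of its donor's reads in WT cells and 89.2% ± 10.1 in K700E cells (SD, n = 3; limma adjusted p = 0.00650). Its adjusted p was 0.0842 when limma was fitted to the 2 DMSO groups alone. The junction at chromosome 22, 20958351 to 20958602 (minus strand), went from 7.23% ± 2.47 to 92.5% ± 3.22 (limma adjusted p = 0.000368). Of the largest falls, the junction at chromosome X, 55101548 to 55102466 (plus strand), held 84.0% ± 0.661 of the acceptor's reads in WT cells and was listed at 0 in every K700E library (limma adjusted p = 1.29e-05). That at chromosome 7, 83631363 to 83634654 (minus strand), went from 100% in each WT library to 24.2% ± 6.60 (limma adjusted p = 0.000814). Among spliced reads only, this chromosome 7 junction did not pass the usage filter and was not tested. As its share of all reads was well above the filter's lower limit, it can only have exceeded the upper limit there. Its fall may thus be largely a gain of unspliced reads, and a switch to another junction was not shown.

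Intron retention under DMSO was compared over 104520 introns. The mean unspliced share was 6.55% ± 0.0588 in WT and 6.67% ± 0.0910 in K700E cells, a difference of 0.118 points (two-sided exact permutation test, p = 0.2, where 3 against 3 cannot go below 0.1). Retention was higher in K700E cells at 304 introns and lower at 209, of 44263 tested with limma. Both the total and the balance depended on the setting: 166 higher and 75 lower (241 in all) with limma on percent values, 197 and 118 on log-odds, and 88 and 97 with the lower of the unspliced shares. Without WT DMSO replicate 1 it was 233 and 134, and without K700E DMSO replicate 2 it was 170 and 170. Of the 474 lower junctions, 206 (43.5%) had an unspliced share at least 10 points higher in K700E cells. The limma test recovered 3.03% of rare simulated junction changes of 40 points and 45.5% of such intron changes. Of the few junction calls in that simulation, 2 true and 3 false, 60% were false. So few calls do not give the false share of the real comparison, where 1522 junction tests had a limma adjusted p below 0.05. For rises that start from a moderate share, as simulated, the counts may miss many changes. Falls were not simulated. Rises from a share near that of the largest real junction rises in WT cells were not simulated. Fitting only the 2 DMSO groups gave 378 junctions and 132 introns, 87 of these higher and 45 lower.

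The second question was where the acceptors used more in K700E cells lie. Of 334 such junctions compared at a shared donor, 150 (44.9%) ended 10 to 30 nt upstream of that donor's most used acceptor. The median distance in this window was 17 nt. Of the others, 979 of 37710 tested junctions that were not the most used lay there (2.60%), an odds ratio of 30.6 (Fisher's exact test, two-sided, p = 6.88e-138). Junctions that share genes or sites are not independent, which makes this p too small. Another 84 of the 334 acceptors lay more than 100 nt upstream, 79 lay downstream, 18 lay 31 to 100 nt upstream and 3 lay 1 to 9 nt upstream.

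The next comparison asks whether the drug lowers the mutant-associated junctions. A set of 270 junctions ending 10 to 30 nt upstream was chosen with replicates 1 and 2 of the K700E DMSO group against WT DMSO, so its low level in WT cells follows from the choice, and its level in those replicates is raised by it. Its median share of donor reads was 22.4% ± 1.26 in K700E cells under DMSO and 19.9% ± 0.889 with H3B-8800. In WT cells the median was 0.547% ± 0.173 under DMSO and 0.742% ± 0.707 with the drug. The set came from the tested junctions, which needed at least 5 percent in 3 or more of all 12 libraries. Replicate 3 and the treated libraries could thus help a junction to enter it. Against replicate 3, not otherwise used in the choice, the drug difference in K700E cells was -1.15 points, with 1 DMSO library and therefore no test. It was -1.99 points with replicate 2 held out in its place and -0.638 points with replicate 1 held out. Against all DMSO replicates it was -2.46 points (two-sided exact permutation test, p = 0.1, the smallest that 3 against 3 allows), a value that the choice itself lowers. The mean share with the drug was below the value of that held-out replicate at 152 of the 270 junctions. Among spliced reads only, a choice made after the data were seen, 289 junctions qualified, and the difference was 1.78 points against replicate 3 and 0.0864 points against all (exact permutation p = 0.9).

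**Figure D1:**
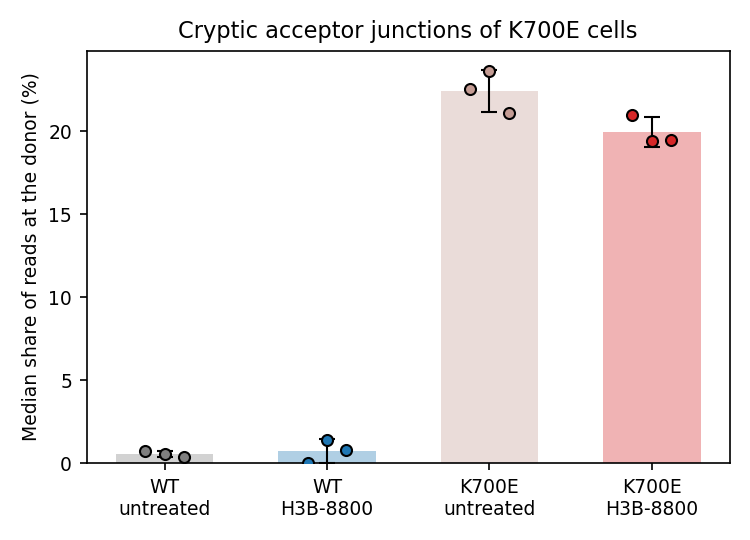
Median share of donor reads (%, vertical axis) of the 270 junctions ending 10 to 30 nt upstream of the usual acceptor, in the 4 groups; untreated means DMSO. Points are libraries, bars are means and whiskers are SD (n = 3). K700E libraries lie between 19.4% and 23.6%, and WT libraries between 0 and 1.41%. The junctions were chosen on WT DMSO and on K700E DMSO replicates 1 and 2, among tested junctions. The usage filter for testing took in all 12 libraries.

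The comparison of H3B-8800 with DMSO in WT cells asks what the drug does to splicing in cells without the mutation. Intron retention was higher with the drug: the mean unspliced share over 104520 introns was 6.55% ± 0.0588 under DMSO and 9.12% ± 0.128 with the drug, a difference of 2.58 points. Retention was higher at 6460 introns and lower at 205, of 44263 tested (limma, adjusted p below 0.05 and at least 10 points). The share of introns retained at 10% or more was 15.7% ± 0.146 under DMSO and 23.3% ± 0.323 with the drug. Exon-skipping junctions rose too, and made up 3519 of the 5133 higher junctions (68.6%) against 14.2% of those tested. With junctions most used at both ends under DMSO left out, a choice made after the data were seen, the shares were 78.7% and 30.7%.

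For both retention measures every treated library lay above every DMSO library (two-sided exact permutation test, p = 0.1 each, the smallest possible). In all, 15131 junctions fell. At 7307 of them (48.3%) the unspliced share at the same site rose by 10 points or more. The intron at chromosome 11, 94703261 to 94704140 (hg19, minus strand), was retained at 17.5% ± 12.3 under DMSO and 90.2% ± 13.0 with the drug (limma adjusted p = 0.0140). The intron at chromosome 6, 30891283 to 30892130 (plus strand), went from 22.7% ± 19.6 to 90.6% ± 8.96 (limma adjusted p = 0.0126). The largest falls in retention varied more between libraries. At chromosome 7, 6861996 to 6862943 (minus strand), retention went from 57.9% ± 37.7 to 14.9% ± 9.16 (limma adjusted p = 0.0254). At chromosome 16, 58019846 to 58021299 (plus strand), it went from 53.9% ± 21.3 to 11.1% ± 19.2 (limma adjusted p = 0.0329). Both falls lost the threshold with limma on percent values and with limma on only the 2 groups (adjusted p = 0.0735 and 0.0947). Of 6 settings that left out 1 library, they lost it in 4 (chromosome 7) and 5 (chromosome 16), with adjusted p up to 0.0868 and 0.110. With the lower of the unspliced shares, that on chromosome 16 was -30.6 points (adjusted p = 0.201). That on chromosome 7 was -22.0 in place of -43.0 points without WT DMSO replicate 1. With shares among spliced reads only, 5631 junctions were higher and 8734 lower, so the lower ones made up less of the total.

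The same comparison in K700E cells showed retention and exon skipping again. The mean unspliced share was 6.67% ± 0.0910 under DMSO and 10.1% ± 0.110 with H3B-8800, a difference of 3.45 points. Retention was higher at 9454 introns and lower at 186 of 44263 tested (limma, adjusted p below 0.05 and at least 10 points). The share of introns retained at 10% or more was 15.9% ± 0.262 under DMSO and 26.1% ± 0.334 with the drug. Among 6868 higher junctions, 4703 (68.5%) skipped an exon.

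Every treated K700E library lay above every K700E DMSO library in both retention measures (two-sided exact permutation test, p = 0.1 each, the smallest possible). There were 22522 lower junctions, and at 11826 (52.5%) the unspliced share rose by 10 points or more. Here too some other share at the site had to rise. The intron at chromosome 11, 43904282 to 43904634 (hg19, plus strand), went from 18.1% ± 5.21 to 84.9% ± 2.52 (limma adjusted p = 3.27e-05). The same intron went from 7.59% ± 0.867 to 63.8% ± 4.82 in WT cells (limma adjusted p = 3.42e-05). The intron at chromosome 1, 16531672 to 16531845 (minus strand), went from 12.2% ± 0.518 to 76.5% ± 13.3 (limma adjusted p = 3.95e-05). Falls were found at chromosome 11, 555112 to 555304 (minus strand), from 64.8% ± 21.1 to 26.8% ± 6.67 (limma adjusted p = 0.0498). At chromosome 16, 28403177 to 28403300 (minus strand), retention went from 68.1% ± 28.4 to 30.4% ± 8.79 (limma adjusted p = 0.0288). Both falls lost the threshold with limma on percent values and on log-odds (adjusted p = 0.0563 and 0.182 for log-odds). Of 6 settings that left out 1 library, they lost it in 5 (chromosome 11) and 4 (chromosome 16), with adjusted p up to 0.148 and 0.101. That on chromosome 16, -37.6 points, was -21.7 points without K700E DMSO replicate 3 and -58.3 points with the lower of the unspliced shares. With shares among spliced reads only, 7465 junctions were higher and 11849 lower, a total of 19314.

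**Figure D2:**
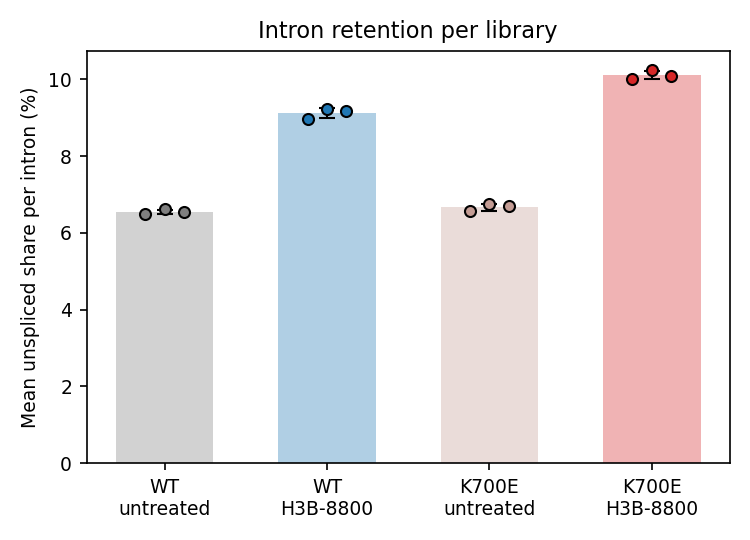
Mean unspliced share per intron (%, vertical axis) over 104520 introns in the 4 groups; untreated means DMSO. Points are libraries, bars are means and whiskers are SD (n = 3): drug-treated means are 9.12% and 10.1%, against 6.55% and 6.67% under DMSO.

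**Figure D3:**
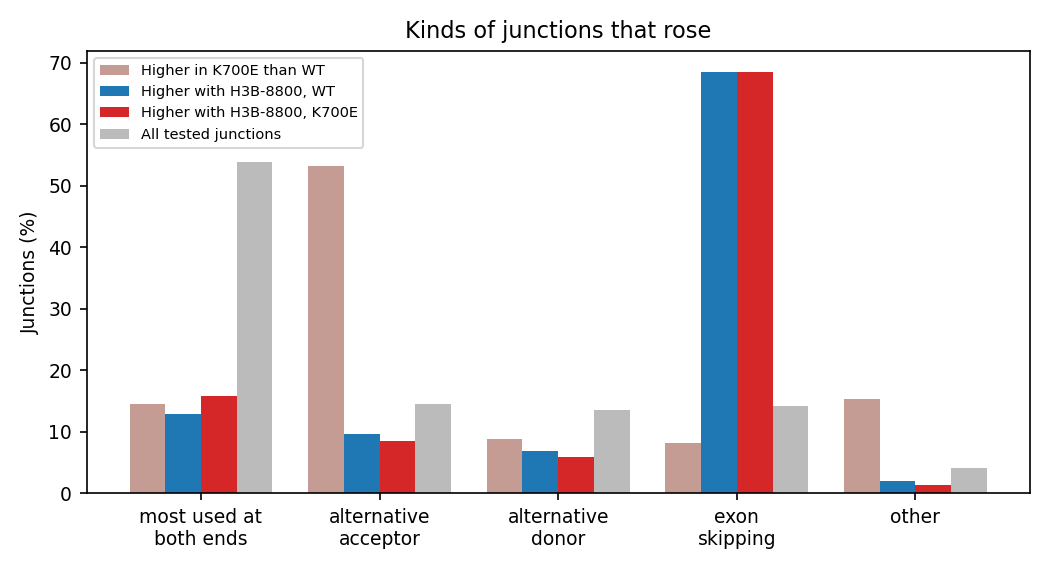
Share (%, vertical axis) of junctions in each class (horizontal axis) among those higher in K700E under DMSO, those higher with H3B-8800 in each genotype, and all 137948 tested. Alternative acceptors make up 53.2% of the junctions higher in K700E cells, and exon skipping 68.6% and 68.5% of those higher with the drug.

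The drug differences in the 2 genotypes come from separate libraries, and their calls overlapped. The spread of each feature came from one fit of all 12 libraries, so features of low spread are more readily called in both. The number for independent lists can therefore be too low a reference. Of the 6460 introns retained more in WT cells, 5175 (80.1%) were also called in K700E cells, where independent lists would share 1380. Retention was lower in both at 36 introns, against 0.861 for independent lists. The changes correlated across introns at r = 0.667, although introns are not independent replicates.

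Introns that gained retention were shorter than the others. In WT cells the median length was 493 nt for the 6460 introns that rose and 1126 nt for the 37598 tested introns that did not pass. In K700E cells the medians were 538 nt for 9454 introns and 1183 nt for 34623. Both differences had p = 1e-05 in a two-sided permutation test with 100000 resamples, the smallest it can give, over introns that are not independent. Matching on retention under DMSO left medians of 493 against 1163 nt and 538 against 1250 nt. The mean difference between drug and DMSO was 5.20 points in WT and 6.48 points in K700E cells for introns of up to 100 nt, and 0.737 and 1.15 points for those over 10000 nt. The gap was smaller between neighbours, a comparison chosen after the result was seen. At 4338 exons between an intron of at most 200 nt and one over 2000 nt, the short introns rose by 3.17 points in WT cells. The long ones rose by 2.38 points. In K700E cells the rises were 4.18 and 3.19 points.

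**Figure D4:**
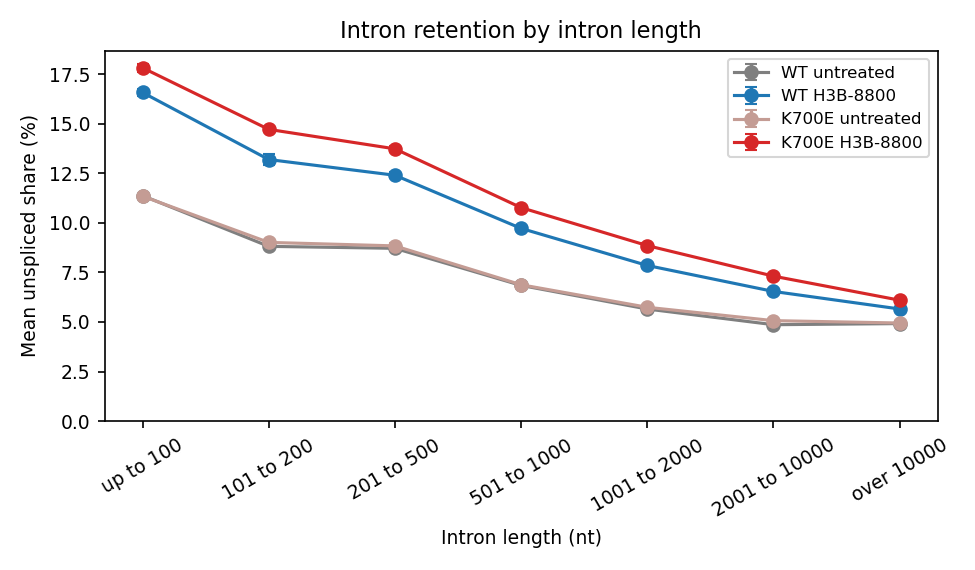
Mean unspliced share (%, vertical axis) of introns in 7 length classes (nt, horizontal axis, unequal class widths) in the 4 groups; untreated means DMSO. Points are means of 3 libraries and whiskers SD, mostly smaller than the points: the distance between drug and DMSO narrows from 5.20 and 6.48 points at up to 100 nt to 0.737 and 1.15 points over 10000 nt.

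The last comparison asks whether the response to H3B-8800 differs between the genotypes. Few single features passed: 42 junctions rose more (or fell less) in K700E cells and 68 the reverse, of 137948 tested, and 6 introns rose more and 3 less, of 44263 (limma interaction term, adjusted p below 0.05 and at least 10 points). The drug difference in mean retention was 0.874 points larger in K700E than in WT cells, which 38 of 400 relabellings of the genotypes within each treatment matched or passed (permutation p = 0.095). With 3 treated libraries per genotype that separate fully, at 8.98% to 9.22% in WT and 10.02% to 10.24% in K700E cells, and a DMSO difference this small, that p stays near 0.1 whatever the size of the difference. In length classes, it was larger in K700E cells by 1.27 points at up to 100 nt and by 0.414 points over 10000 nt.

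The intron at chromosome 6, 31655073 to 31655274 (hg19, minus strand), moved in opposite directions. Its retention went from 53.7% ± 4.12 to 18.5% ± 2.34 with the drug in WT cells and from 40.7% ± 6.80 to 69.9% ± 3.71 in K700E cells (limma interaction adjusted p = 0.00848). At chromosome 11, 6518562 to 6518814 (plus strand), retention went from 70.3% ± 3.09 to 90.5% ± 6.73 in WT and from 33.7% ± 4.52 to 89.2% ± 2.40 in K700E cells (limma interaction adjusted p = 0.0455). At chromosome 8, 79848778 to 79850121 (minus strand), it was listed at 0 in each WT DMSO library and was 44.1% ± 9.99 with the drug. The K700E values there were 37.5% ± 11.02 and 42.2% ± 21.1 (limma interaction adjusted p = 0.00848). With the lower of the unspliced shares at its ends this call was lost, as the difference went from -39.3 to -6.48 points (limma adjusted p = 0.826). At chromosome 18, 74607242 to 74610974 (plus strand), WT cells went from 0 in each library to 23.6% ± 11.02. In K700E cells it went from 3.63% ± 0.338 to 0 in each library (limma interaction adjusted p = 0.00848). The junction count moved between 52 and 278 when single libraries were left out, and its balance turned: 94 to 131 higher and 49 to 87 lower without single WT H3B-8800 replicates, but 53 to 61 higher and 174 to 218 lower without single K700E H3B-8800 replicates. The chromosome 11 intron passed in 3 of 12 settings that left out 1 library and the other 3 introns in all 12, while with limma on percent values those on chromosomes 11, 8 and 18 had adjusted p = 0.110, 0.354 and 0.200. With limma on log-odds, those on chromosomes 11 and 8 had 0.637 and 0.114, and with the lower of the unspliced shares that on chromosome 11 had 0.201. The intron on chromosome 18 could not be tested that way, as its lower share reached 5% in fewer than 3 libraries. With the replicate number as a block in limma, none of these introns passed. Adjusted p was 0.0695 on chromosomes 6, 8 and 18 and 0.153 on chromosome 11.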

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

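The comparison of neighbouring introns, the spliced shares and the lower of the unspliced shares were tests chosen only after the result was seen. The test of the difference between genotypes singled out 110 junctions and 9 introns whose response to H3B-8800 differed between WT and K700E cells. Of the introns given by coordinates, that at chromosome 6, 31655073 to 31655274, had a drug effect 64.5 points higher in K700E cells, and that at chromosome 11, 6518562 to 6518814, one 35.3 points higher. The effect at chromosome 8, 79848778 to 79850121, differed by -39.3 points and that at chromosome 18, 74607242 to 74610974, by -27.3 points. At chromosome 11 the untreated genotypes already differed, at 70.3% in WT and 33.7% in K700E cells. With the drug they reached 90.5% and 89.2%, so the difference in effect there follows from the DMSO levels. At chromosome 8 the untreated genotypes also differed (0 against 37.5%), and the lower of the unspliced shares at the intron's ends gave a difference of -6.48 points. For the difference in response, 2 of 50 splits drawn from the 200 possible, the real one included, gave as many junctions as the real 110, and 2 of 50 gave as many introns as the real 9. In each case the other one exchanged the genotype labels of the DMSO libraries alone, with 5602 junctions and 1753 introns. That exchange turns the contrast into the sum of the genotype differences under DMSO and under the drug, so its count is set by construction. Of the remaining splits, the highest gave 108 junctions and 7 introns, close to the real counts.

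The drug difference in mean retention was 0.874 points larger in K700E than in WT cells. The mutation, a difference between the cell clones and a difference between library batches cannot be told apart, since the labels give 1 isogenic line per genotype and no batch. The mutation stays a candidate explanation among these.

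Retention was higher with H3B-8800 in every treated library of both genotypes, and a biological explanation, the drug itself, stands against technical ones. A lower depth of the treated libraries is argued against only as far as sites with reads stand for depth, which is unknown. The slope of retention on sites with reads within groups gives at most 5.60% of the rise, at the upper end of 2 standard errors, in the genotype where it is larger. Sites with reads varied less within groups than between drug and DMSO, so the slope was extended beyond its own range. DNA or unprocessed RNA carried over into the treated libraries may contribute, and stays open. It would raise both introns beside an exon alike, and over 4338 exons the short intron rose more than the long one by 0.793 ± 0.175 points in WT and 0.983 ± 0.138 points in K700E libraries (SD, n = 3). That is above 0 in all 6 treated libraries, from 0.608 to 1.06 points, while both means lie within the bound of 1 point set for carry-over.

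Most junctions that rose with the drug skip an exon, and unspliced reads in the total of the deposited percentages do not explain this: by spliced shares, 70.3% of the higher junctions in WT and 70.0% in K700E cells skip an exon, against 18.1% of those tested. A hypothesis was that exons are skipped where the introns beside them may be retained. For each intron beside a skipping junction, the mean rise of introns of like length and untreated retention was subtracted from its rise. The median result was -0.00803 points over 6148 introns in WT cells and 0.0878 points over 8094 in K700E cells. Both lie under the 1 point the hypothesis needed. Rises are skewed, however (median 1.70 and mean 3.63 points beside skipping junctions in WT cells). A median taken against a mean then comes out low, so this test cannot decide. The mean differences were 0.884 points in WT and 1.24 points in K700E cells, so the hypothesis is left open, also for a smaller set of such introns with larger rises. The drug as the cause of the skipping was tested only through the groups compared.

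Other splits of the samples were counted for each test. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and 1 of the 10, the real one, gave as many calls in each comparison of 2 groups. For the mutation the real split gave 985 junctions and 513 introns, and the highest other 30 and 5. For the drug in WT cells it gave 20264 and 6665 against 46 and 7. For the drug in K700E cells it gave 29390 and 9640 against 30 and 3. Every other split mixes libraries of both groups, so a real difference between them adds to the spread within groups. Low counts of the other splits follow from that and do not measure how many calls arise by chance.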

How the results depend on the processing

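Settings that changed the measure, the filter or the groups fitted were chosen after the data were seen. Mean retention kept its direction in every left-out-replicate setting (0.0804 to 0.169 points for the mutation, 2.53 to 2.65 for the drug in WT, 3.39 to 3.50 in K700E, 0.801 to 0.924 for the difference), as did the acceptor distance (42.6% to 49.1%) and the median intron length difference (-641 to -628 nt in WT and -645.5 to -638 nt in K700E cells, a setting added late). Depth is unknown, which limits all values.

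Several counts moved by over 1.5 times. At 20 points or more there were 576, 10162 and 15413 junctions for the mutation, the drug in WT and the drug in K700E, and 196, 2427 and 4031 introns; at 5 points, 10829 and 14889 introns for the drug in WT and K700E. These follow from the threshold. Fits of only the 2 groups, with fewer samples, gave 378 junctions and 132 introns for the mutation. The lower of the unspliced shares gave 185 introns for the mutation, 4339 for the drug in WT and 15 for the difference between genotypes. Limma on percent values gave 241 introns for the mutation, and 39 junctions and 5 introns for the difference; log-odds gave 315 introns, and 53 and 4. No usage filter gave 315 introns for the mutation, and 325 junctions and 17 introns for the difference. Spliced shares gave 19314 junctions for the drug in K700E and 263 for the difference. Apart from the thresholds and the smaller fits, the cause was not tested.

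Leaving out single libraries gave 603 to 659 junctions for the mutation, where each library but K700E DMSO replicate 3 lowered the count by over 1.5 times (614, 653 and 604 without WT DMSO replicates 1, 2 and 3, and 603 and 617 without K700E DMSO replicates 1 and 2). It gave 314 to 373 introns for the mutation (314 and 340 without K700E DMSO replicates 1 and 2). For the difference between genotypes, junctions ranged from 52 to 278: 52, 61 and 64 without WT DMSO replicates 1, 2 and 3, and 67, 57 and 55 without those of K700E DMSO. They were 218 without WT H3B-8800 replicate 2, and 278, 239 and 227 without K700E H3B-8800 replicates 1, 2 and 3. Introns ranged from 6 to 18: 16 without WT DMSO replicate 3 or K700E DMSO replicate 3 and 18 without WT H3B-8800 replicate 2. The cause was not tested.

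Replicate numbers did not pair the samples: deviations of same-numbered libraries correlated between -0.0068 and 0.0060 over 18 pairs. With the replicate number as a block, junctions were 532, 18184, 27848 and 4 for the mutation, the drug in WT, the drug in K700E and the difference, and introns 343, 6450, 9474 and 0. The unblocked limma fit had 3622 introns at an unadjusted p under 0.05 for the difference.

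The drug difference of the mutant-associated junctions, -2.46 points over 270 junctions, was 0.0864 points among spliced reads (exact permutation p = 0.9). There the medians were 23.9% ± 1.49 under DMSO and 24.0% ± 1.32 with the drug, over 289 junctions. With unspliced reads out of the total, no drop was thus seen, although the set of junctions was not the same. Values against all replicates include those used for the choice. Against the held-out one, which entered the choice only through the usage filter, the difference was -1.15, -1.99 and -0.638 points, and 1.78 among spliced reads. No single junction or intron given by coordinates reversed. Those of the mutation passed in 42 of 43 settings, which hold no spliced share for the chromosome 7 junction, as it was not tested that way. Those of the drug passed in 28 of 44 in WT and 29 of 44 in K700E cells, and those of the difference in 43 of 63. Tests on counts and per gene, read minimums, annotated features only, matching on mean count and gene lists need counts or gene names and were not run.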

Other observations

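Changes of junctions with the drug also overlapped between genotypes, over tests at donors and acceptors. Of the 7854 tests higher in WT cells, 5323 (67.8%) were higher in K700E cells too, where independent lists would share 390. Of the 18805 lower in WT cells, 13987 (74.4%) were lower in K700E cells, against 2570 for independent lists. The differences come from separate libraries, but the spread came from one fit, so independent lists can be too low a reference here too. Tests at shared sites are not independent.

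Alternative acceptors were 496 of 5133 higher junctions in WT cells (9.66%) and 584 of 6868 in K700E cells (8.50%), against 14.5% of those tested.

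Between the shortest and the longest introns, the drug difference in mean retention fell from class to class. In WT cells it was 4.38 points above 100 and up to 200 nt, 3.69 points up to 500 nt, 2.88 points up to 1000 nt, 2.20 points up to 2000 nt and 1.68 points up to 10000 nt, each class starting where the one before ends. In K700E cells it was 5.70, 4.90, 3.89, 3.11 and 2.25 points in the same classes. Under DMSO, mean retention was also higher in short introns, at 11.4% ± 0.0816 up to 100 nt and 4.92% ± 0.0884 over 10000 nt in WT cells (SD, n = 3).

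Alternative donors made up 45 of the 511 junctions higher in K700E cells under DMSO (8.81%), 352 of 5133 with the drug in WT cells (6.86%) and 404 of 6868 in K700E cells (5.88%), against 13.5% of those tested.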
